A study of Gallus gallus with 6 samples.

How the data were processed

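Total RNA of 6 chicken neural crest culture samples, 3 in media and 3 in 100 uM homocysteine, was measured on 1-colour Affymetrix chicken arrays, per the labels. The deposited values are linear intensity values per probe set, given to 1 decimal with no floor. Per the submitters' processing notes the tool was RMA, with no version. The values as deposited do not have the form of RMA output: they are linear, their quantiles differ between arrays, and the mean after trimming 2% at each end is 500.1 on every array, the form of Affymetrix MAS5 or GCOS signals. The background step, the summary of probes and detection calls are not given in the sources used here. The label field names Cy3 and Cy5, which does not match an array of 1 colour; the values were treated as 1 channel.

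The design had been written for log2 values, with log2 of the table as the provision for a linear one, so log2 of each deposited intensity was taken, with no pseudocount and no further normalization. Groups and replicate numbers came from the sample titles. The 96 Affymetrix control sets and 57 reporter sets (exogenous sequences) were left out of the tests, leaving 38382 probe sets; setting aside the reporters was decided after the data were examined. For each array the 95th percentile of the reporter sets, between 53.2 and 84.9, served as its background. A probe set above it on at least 3 arrays, as 19257 were (50.2%), is called above background. This background and its use were also chosen after the data were examined. No probe set was removed by it in the tests reported as main results. In the report no fold is given where a group is below background on every array, except as a lower bound; log2 changes of such genes are listed only to show how their sign depends on the processing.

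Homocysteine was compared with control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, no array weights, two-sided), with Benjamini-Hochberg adjustment over all 38382 probe sets and a threshold of 0.05. For genes, the probe set with the highest mean over all 6 arrays was taken, giving 13009 genes. The 32 gene lists had been fixed before the data were examined; 991 of their 1232 genes were measured under the same symbol, and each list had at least 8. Lists were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, which tests whether a list's genes move one way on balance. Members were also adjusted over the list alone. Errors are SDs over 3 arrays on the linear scale, and intervals are 95% intervals of the limma log2 change. The number of arrays, the signal level and the pooling of variance limit the precision. At the median the interval reached 0.79 in log2 to either side of the change for probe sets above background on all 6 arrays. It reached 1.89 to either side for those not above background on 3. The fit moderates each spread toward a value pooled over all 38382 probe sets, dim ones included. This widens the interval of a bright probe set with little spread of its own. INSIG2, at 1524 ± 56.17 in control and 1212 ± 51.59 with homocysteine (SD, n = 3 each), had an interval from -0.93 to 0.27.

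Gene symbols came from the platform annotation, which can be old. It gave 1 symbol for 27168 probe sets, several for 177 and none for 11037. Of the 27168, 26853 were found by gene number in a RefSeq gene table of assembly GRCg7b, used for names only. Lists were matched by exact symbol, a choice made after the data were examined because synonyms gave wrong pairs. Of 2800 genes with several probe sets above background on all 6 arrays, 1515 had log2 changes of opposite sign among them, with a median range of 0.21.

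The rule for named genes, fixed before the data were examined, took the 12 probe sets per direction with the largest change past the threshold and no overlap between groups. Where fewer passed, it filled the places by the smallest p among log2 changes of at least 0.5 with no overlap, 1 plain gene symbol each (clone names, KIAA names included, were passed over). From each list it took up to 4 members past the threshold, or the 2 with the smallest p where none passed. It always took 10 genes of homocysteine metabolism and neural crest, of which 8 were measured under their symbols. Genes named outside it are marked as picked after their values were seen.

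Alternatives fixed before the data were examined were the replicate block, filters on dim probe sets, quantile normalization, centring, a trended and robust variance, array weights, other summaries per gene, an unmoderated statistic per probe set, a test against 1.2-fold, other thresholds and leaving out each array. Raising dim values to background, keeping only probe sets above it, and the fits that handle the replicate 1 arrays were added after the data were examined. The fit was tested on data simulated from the real means and the moderated spreads of the fit, 20 times with 200 changed probe sets above background among 38382. It called 0% of 2-fold, 0% of 4-fold, 57.6% of 8-fold and 95.4% of 32-fold changes. Restricted to the 19257 probe sets above background it called 0% of 2-fold, 70.4% of 4-fold and 92.5% of 8-fold changes. Camera, on simulated data for 13009 genes, called a list of adhesion and migration genes shifted by -0.5 in log2 in 100% of 20 runs and 0 lists where none was shifted; these simulated genes vary independently, which real genes of a list do not. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.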

Results

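Chicken neural crest cells, the migratory cells that leave the dorsal neural tube, were grown out of neural tube explants from stage 9+ embryos. After 4 h in culture they were kept in media alone (control, 3 arrays) or in 100 uM homocysteine, a sulfur amino acid of the methionine cycle (3 arrays), for 6 h. Total RNA of each culture sample was hybridised to an Affymetrix chicken array, which reads 38535 probe sets. The median intensity per array lay between 57.7 and 70.9. Between 17435 and 20461 of the 38382 chicken probe sets were brighter than the reporter probe sets, which match no chicken transcript. The only comparison in the design, homocysteine against control, asks which transcripts change in neural crest cells within 6 h of homocysteine. The labels number the arrays of each group from 1 to 3 and do not say whether they came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical. In the moderated fit this spread is in part pooled over all probe sets, dim ones included.

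Neural crest regulators were expressed in both groups, and no difference between the groups was detected for any of them. SOX10, a transcription factor of migrating neural crest, had an intensity of 4239 ± 952.5 (SD, n = 3) in control and 4386 ± 792.4 (SD, n = 3) with homocysteine, a log2 change of 0.06 with a 95% interval from -0.72 to 0.84. FOXD3, an early neural crest specifier, gave 1311 ± 458.5 and 1591 ± 829 (SD, n = 3 each). SNAI2, a repressor of epithelial genes in cells leaving the neural tube, gave 3100 ± 2014 and 2404 ± 1517 (SD, n = 3 each), and SOX9 205.7 ± 168.9 and 213.3 ± 197.6 (SD, n = 3 each). The intervals of their log2 changes, which ignore the replicate numbers, were wide, from -2.58 to 1.94 for SNAI2 and from -2.08 to 2.07 for SOX9. By replicate number, SNAI2 went from 805.7 to 711.3, 3915.2 to 3639.9 and 4578 to 2861.5, lower with homocysteine each time. SOX9 went from 79 to 102.2, 140.6 to 96.3 and 397.4 to 441.4. The unadjusted p of SNAI2 was 0.74, or 0.257 with the replicate number as a block (limma). TFAP2A, a transcription factor of the neural plate border, gave 194.4 ± 33.05 and 189.6 ± 27 (SD, n = 3 each). The adjusted p of all 5 genes was 0.9999 (limma, Benjamini-Hochberg). Of 39 measured neural crest specifiers and markers, 0 passed the threshold, 23 had a positive and 16 a negative log2 change, and the median was 0.05. The pair with the smallest p in this list were CSRNP1, a transcription factor gene, and MEF2C. CSRNP1 gave 1941 ± 108.5 in control and 1278 ± 171.1 with homocysteine (SD, n = 3 each, adjusted p = 0.9999 in limma). MEF2C was above background on 1 control array and on no homocysteine array. A dimmer probe set of CSRNP1 gave 845.8 and 754.7.

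**Figure D1:**
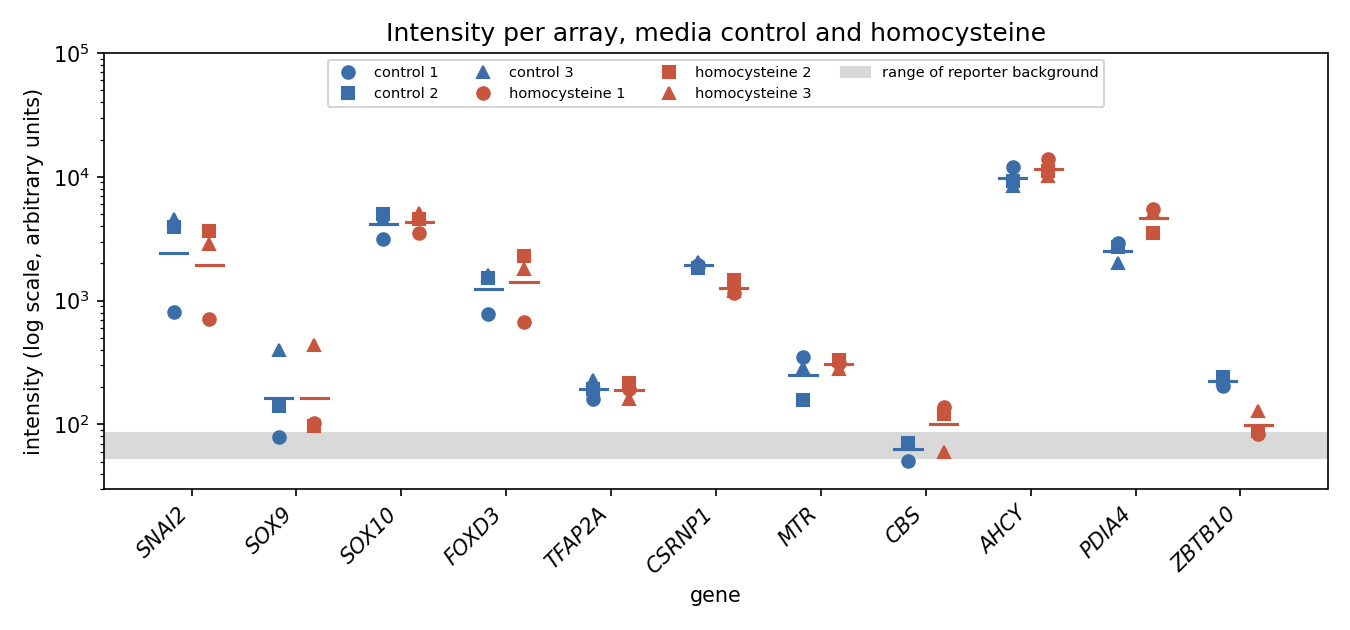
Intensity (log axis, arbitrary units) of 11 genes on each of the 6 arrays, with blue for control, red for homocysteine, the marker shape for the replicate number and a bar for the mean of the log2 values; the grey band is the range of the reporter background over the arrays. SNAI2 lies at 805.7 and 711.3 on the replicate 1 arrays of the control and homocysteine groups and between 2861.5 and 4578 on the other 4.

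Genes that make, use or clear homocysteine gave no call either. AHCY, which splits S-adenosylhomocysteine into homocysteine and adenosine, was bright in both groups, at 9923 ± 1901 in control and 11760 ± 1901 with homocysteine (SD, n = 3 each, adjusted p = 0.9999). A second, dimmer AHCY probe set had the opposite sign, at 468.2 and 336.3. MTR, which methylates homocysteine to methionine, gave 264.6 ± 97.11 and 308 ± 26.29 (SD, n = 3 each). CBS, which joins homocysteine to serine, lay near background, above it on 2 of 3 control and 3 of 3 homocysteine arrays, at 63.83 ± 11.43 and 106.2 ± 40.59 (SD, n = 3 each). Of 33 measured genes of homocysteine and one-carbon metabolism, 0 passed, 17 had a positive and 16 a negative log2 change, and the median was 0.0035. The smallest p in this list belonged to FOLR1, a folate receptor gene that was above background on 1 control and 2 homocysteine arrays, and DNMT1, a DNA methyltransferase gene, at 135.4 ± 40.29 and 212 ± 54.98 (SD, n = 3 each).

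In adhesion, protease and migration genes, 0 of 67 measured members passed the threshold, with 27 positive and 40 negative log2 changes and a median of -0.02. EPHA4, an ephrin receptor gene, was above background on all 3 control arrays, at 156.9 ± 50.23 (SD, n = 3), and on none of the homocysteine arrays, at 47.63 ± 23.65 (SD, n = 3). This puts control at least 2.14-fold above homocysteine, with an adjusted p of 0.948, so the difference did not pass. The bound sets the mean of the control log2 values against a value per homocysteine array. That value is the higher of the probe set's own value and the lowest value above background. The bound allows for dim signal only and not for the spread between arrays. The background was higher on homocysteine 1 and 2 (77.16 and 84.88) than on any control array (53.68 to 65.62). EPHA4 was read at 74.6 on homocysteine 2, above the background of every control array. The other member with the smallest p, ADAM19, was above background on 1 of the 6 arrays. Extracellular matrix genes had 20 positive and 38 negative log2 changes among 58 measured members, 0 of which passed, with a median of -0.12. MMP2, a matrix protease gene, gave 1050 ± 387.3 and 784.1 ± 51.02, and CDH2, which encodes N-cadherin, 8940 ± 684.6 and 8137 ± 1001 (SD, n = 3 each). MMP2 and CDH2 were picked after their values were seen.

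Stress and biosynthesis genes gave no call. Of 26 measured genes of the unfolded protein response 0 passed, 8 had a positive and 18 a negative log2 change, and the median was -0.07, or -0.13 to -0.015 over leaving out each array. HSPA5, the major chaperone of the endoplasmic reticulum, gave 20040 ± 2083 in control and 20010 ± 1556 with homocysteine (SD, n = 3 each). Among 24 amino acid response genes the transcription factor gene ATF4 gave 7341 ± 2581 and 6452 ± 1733, and its target ASNS 5701 ± 1164 and 6300 ± 417.9 (SD, n = 3 each). HSPA5, ATF4 and ASNS were picked after their values were seen. Cytosolic ribosomal protein genes had 54 positive and 8 negative log2 changes among 62 measured members, with a median of 0.08. Respiratory chain genes had 42 positive and 16 negative, with a median of 0.06. These medians depended on the scaling: the ribosomal one was 0.0074 with quantile normalization and 0.025 with arrays centred on their medians, and ranged from 0.021 to 0.16 over leaving out each array, and the respiratory chain one was 0.032 and 0.0068 and ranged from -0.064 to 0.22. Neither list passed the test of lists (limma camera, adjusted p = 0.844 for both; 0.984 with an estimated correlation), and 0 of their members passed the threshold.

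Lists of other cell types that an explant could hold gave no call. Neuronal genes had 12 positive and 7 negative log2 changes, with a median of 0.16 and an adjusted p of 0.844 in camera. For mesoderm and somite, surface ectoderm and epithelium, blood and endothelium, endoderm and cardiac muscle the adjusted p was 0.985. DBH among the neuronal genes and TCF15 among the mesodermal genes were the 2 members past 0.05 when adjusted over the list alone, at 0.00265 and 0.0209, and 0 members of any list passed over all genes tested. Neither gene was above background on any array. DBH was read at 14.43 in control and 53.03 with homocysteine, and TCF15 at 48.6 and 7. TBXT, a mesoderm transcription factor gene, was measured on every array, at 416.1 ± 164.2 in control and 898.2 ± 511.1 with homocysteine (SD, n = 3 each, adjusted p = 0.9999). VWF, an endothelial gene, was above background on all 3 homocysteine arrays and on no control array. By the bound used for EPHA4, it was at least 1.56-fold higher with homocysteine, with an adjusted p of 0.924 (limma).

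**Figure D2:**
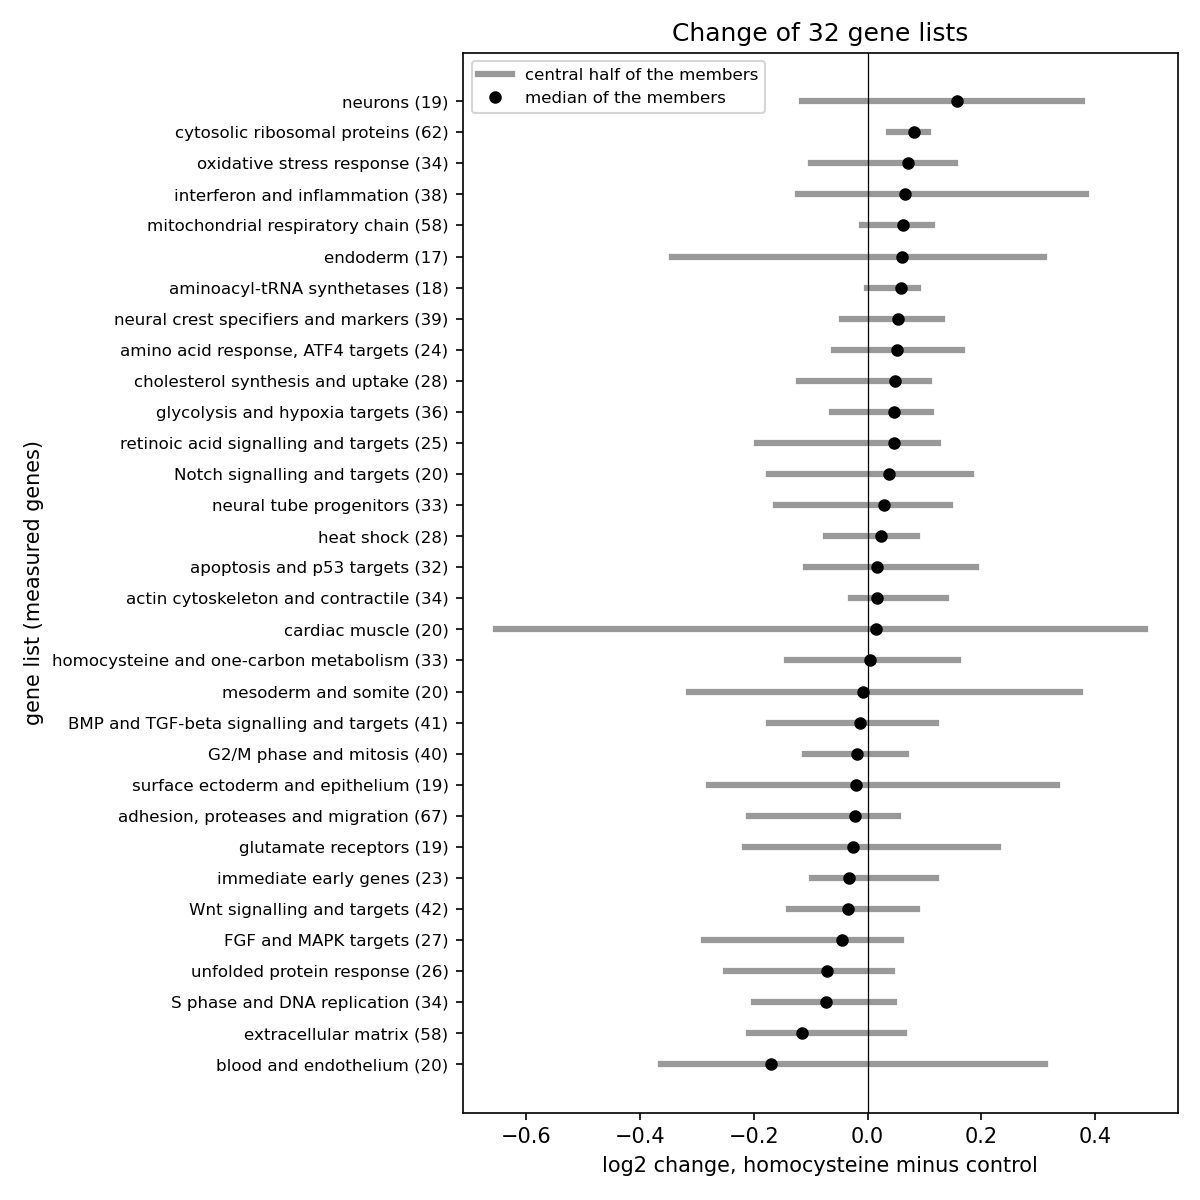
Log2 change with homocysteine (horizontal axis, homocysteine minus control) for each of 32 gene lists (vertical axis, measured genes in brackets); points are medians over the members and grey bars run from their lower to their upper quartile. The bars of 31 lists cross 0, and the ribosomal protein genes, with quartiles of 0.04 and 0.11, did not pass the test of lists.

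Across the array, 0 of 38382 probe sets passed an adjusted p of 0.05 in limma, 0 in either direction, and the smallest adjusted p was 0.295. At an unadjusted p under 0.05 there were 1524 probe sets, 940 higher and 584 lower with homocysteine, against 1919 expected by chance. An unmoderated statistic per probe set also called 0 after adjustment, with 1273 at an unadjusted p under 0.05. The groups did not overlap in 2742 probe sets, or 7.14%, where chance gives 10%. Both chance values assume exchangeable arrays, which these are not, since the replicate 1 arrays stand apart. Of the 1524, 1382 were not above background on 3 arrays. Camera called 0 of the 32 lists, and the smallest adjusted p was 0.844. An exact permutation test of 3 arrays against 3 cannot give a two-sided p below 0.10.

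The genes with the smallest p therefore lay at the dim end of the array, and none passed. The 12 with a positive change were HNRNPK, KCNE2, HORMAD2, TMTC1, CD274, MAGI3, SAMD9L, FHAD1, TFEC, ABCA13, PTBP3 and SEPTIN5. The 12 with a negative change were ZEB1, PTPN13, PITX1, ABHD13, ABLIM1, PCSK7, LRRC66, WAPL, NPFFR2, COLQ, EPAS1 and ARHGEF33. In each direction 10 of the 12 were not above background on any of the 6 arrays, and their adjusted p lay between 0.295 and 0.342. Of the 24 genes, 9 had another probe set above background on all 6 arrays, and the brightest of these had log2 changes between -0.16 and 0.28, 1 of the 9 with the sign of the dim set; this was looked up after the values were seen. HNRNPK, an RNA-binding protein gene, was read at 1.8 and 26.83 by the dim set and at 10710 ± 1632 in control and 10310 ± 1353 with homocysteine by the bright one (SD, n = 3 each). ZEB1, a transcription factor gene of mesenchymal cells, was read at 41.37 and 1.9 by the dim set and at 3533 ± 642.9 and 3954 ± 574.7 by the brightest (SD, n = 3 each).

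Among probe sets above background on all 6 arrays, 7 had a log2 change of at least 1 in size, 2 positive and 5 negative. The following genes were picked after their values were seen, and none passed. ZBTB10, a zinc finger gene, gave 226.4 ± 20.14 in control and 100.1 ± 25.19 with homocysteine (SD, n = 3 each), a log2 change of -1.20 with an adjusted p of 0.888. Its brighter probe sets gave 1453 and 1363, and 1768 and 1215. PDIA4, a protein disulfide isomerase gene of the endoplasmic reticulum, gave 2554 ± 484.1 and 4753 ± 1073 (SD, n = 3 each, adjusted p = 0.9999), and a brighter probe set of the same gene gave 8333 ± 1381 and 8611 ± 1517. CSRP3, a muscle LIM protein gene with 1 probe set listed, gave 451.6 ± 181.7 and 798.9 ± 56.62 (SD, n = 3 each). AKAP1, which encodes an anchoring protein of mitochondria, gave 1048 ± 312.8 and 563.9 ± 72.88, and RRM2B, a ribonucleotide reductase subunit gene, 1076 ± 185.6 and 671.1 ± 17.8 (SD, n = 3 each).

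The replicate 1 arrays of both groups stood apart from the other 4. The ratio of 5' to 3' signal of ACTB was 0.0572 on control 1 and 0.059 on homocysteine 1, and between 0.238 and 0.421 on the others. For GAPDH it was 0.318 and 0.324, against 0.456 to 0.694. The first principal component, with 49.2% of the variance among probe sets above background, put the replicate 1 arrays at -70.03 and -63.13 and the other 4 between 7.6 and 48.7. With the replicate 1 arrays as a batch in the fit, 0 probe sets and 0 lists passed, with 1885 probe sets at an unadjusted p under 0.05. Within the other 4 arrays, 0 probe sets and 0 lists passed, with 2107 at an unadjusted p under 0.05. The batch of replicate 1 holds 1 array per group, so it gives no test. The ribosomal median was 0.08 with the batch in the fit and 0.12 within the 4 arrays (adjusted p = 0.465 and 0.28). Without homocysteine replicate 1, the ribosomal and respiratory chain lists passed, with an adjusted p of 0.00536 for both and medians of 0.16 and 0.22, at the preset correlation only (adjusted p = 0.969 for both with an estimated one). The ribosomal list also passed with dim values raised to background (adjusted p = 8.99e-06), again at the preset correlation only (0.974 with an estimated one).

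**Figure D3:**
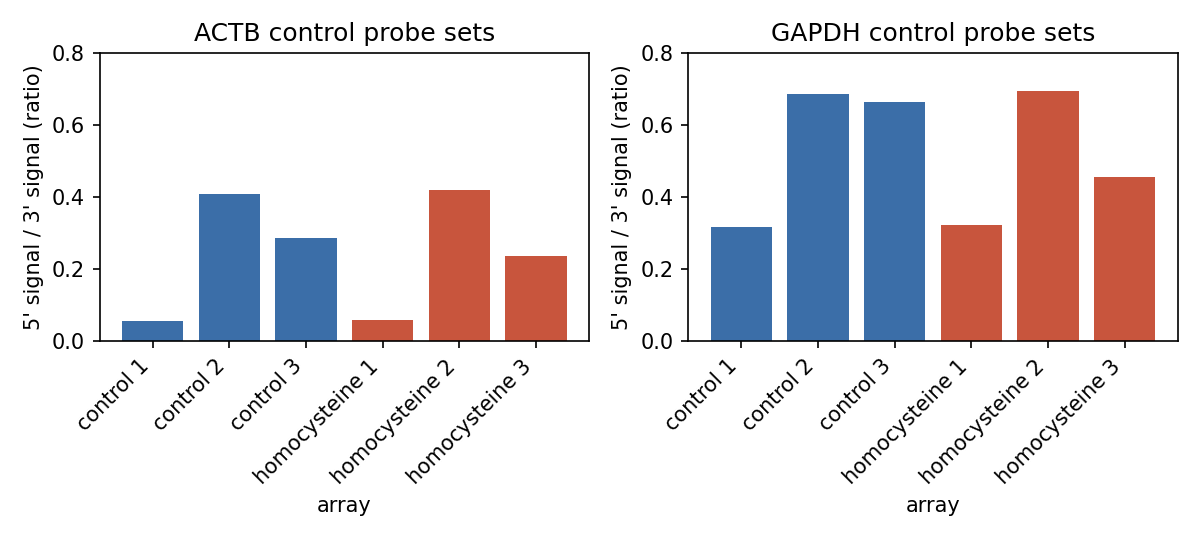
Ratio of 5' to 3' signal (vertical axis) of the ACTB and GAPDH control probe sets on each array (horizontal axis), blue for control and red for homocysteine, 1 value per array. Both replicate 1 arrays lie lowest, at 0.0572 and 0.059 for ACTB and at 0.318 and 0.324 for GAPDH.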

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

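The background, batch and RNA quality settings, and the estimated correlation in 2 of the settings, were chosen after the data were examined; all others had been fixed before. The count of probe sets past the threshold was 0 in the main fit and in every alternative run (other filters, scalings, variance models, gene summaries, thresholds, blocks and each array left out), with 362 to 2107 at an unadjusted p under 0.05. List members past the threshold over all genes were also 0 in the settings run for them (the block, dim genes left out, the mean of all probe sets, a trended and robust variance, each array left out, genes above background and the replicate 1 arrays left out), and 0 to 4 when adjusted over the list alone. The number of lists past the threshold was 0 except in 2 settings. It was 1 with dim values raised to background (the ribosomal proteins, adjusted p = 8.99e-06; range over the alternatives 8.99e-06 to 0.999), where the dim genes lose their spread by construction. Leaving out each array gave 0 to 2 lists, the 2 without homocysteine replicate 1, which leaves 1 replicate 1 array in the control group alone. With the correlation estimated per list both settings gave 0 lists (smallest adjusted p 0.974 and 0.969).

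The replicate numbers did not pair the arrays by the rule fixed beforehand, since deviations from the group means correlated across all probe sets by 0.172, 0.108 and 0.0486 for numbers 1, 2 and 3. As a hint from the data, all 6 arrays correlated best with their own number. Over probe sets above background, a set chosen after the data were examined, numbers 1, 2 and 3 gave 0.586, 0.479 and 0.198. There 5 of 6 arrays correlated best with their own number, and arrays of different number reached at most 0.203. The replicate block left the count of calls at 0, with 2023 at an unadjusted p under 0.05, above the 1919 expected by chance where the main fit was below it, and 0 lists past the threshold. On simulated data the block called 0% of 8-fold and 93.5% of 32-fold changes among 38382 probe sets, and 89.5% of 4-fold changes among 19257 above background.

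No named value or list median that turned its sign had passed the test in the main fit. The respiratory chain list, which turned in 2 settings, passed without homocysteine replicate 1. In 28 of 1428 values of named probe sets the sign turned, 13 of them with the mean of all probe sets of a gene. This share does not measure how firm the signs are. The block and the trended and robust variance cannot alter a log2 change. Genes named for groups without overlap cannot turn when 1 array is left out. With the mean of all probe sets of a gene, log2 changes became -0.45 for SFSWAP, -0.019 for DDX11, -0.15 for AHCY, -0.0798 for SOX10, 0.026 for MSN, -0.14 for SCAP, -0.069 for SOX17, -0.19 for FBLN5, 0.49 for EGLN3, 0.18 for MEF2C, -0.16 for MAP2, 0.19 for HOXB1 and -0.068 for RSPO3; the mean takes in dimmer probe sets for 12 of these 13 genes and, for SFSWAP, a brighter one. Quantile normalization gave 0.016 for TFAP2A. The median of the one-carbon list became -0.0058 without dim genes, -0.018 with quantile normalization, -0.052 with centring and -0.013 without the replicate 1 arrays; the neural crest median became -0.0029 with centring and -0.012 without the replicate 1 arrays, and the unfolded protein response median 0.012 there. Leaving out each array gave ranges of -0.14 to 0.21 for SOX10, -0.18 to 0.71 for FOXD3, -0.041 to 0.53 for MTR, -1.12 to 0.41 for SNAI2, -0.73 to 0.63 for SOX9 and -0.16 to 0.089 for TFAP2A. List medians ranged from -0.11 to 0.094 for one-carbon genes, -0.064 to 0.22 for the respiratory chain, -0.17 to 0.21 for neural crest, -0.14 to 0.00081 for adhesion and migration, -0.13 to 0.010 for extracellular matrix, -0.13 to 0.060 for FGF and MAPK targets, -0.13 to -0.015 for the unfolded protein response, -0.19 to 0.050 for S phase and -0.017 to 0.21 for neurons. The cause of the turned signs was not tested. Only the medians of 10 lists were followed singly, picked after their values were seen; over all 32 lists, 0 to 16 medians turned their sign in a setting. Signal near background limits the 90.7% of the 1524 probe sets that were not above it on 3 arrays.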

Other observations

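The tests of RNA or cDNA length, of labelling, of a response of the 3 lists shared by the cultures and of the counts of probe sets over other splits were chosen after the results they measure were seen. The bounds for labelling and for the 3 lists were made stricter after their values were known; under the earlier bounds both explanations were argued against.

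Several neural crest genes differed more between the replicate 1 arrays and the others than between treatments, and others did not; the 2 differences were not tested against each other. SNAI2 was read at 805.7 and 711.3 on the replicate 1 arrays and between 2861.5 and 4578 on the others, ID1 at 939.5 and 1079.4 against 4070.2 to 7820.8, PAX7 at 294.7 and 264.5 against 891.8 to 1100.6, and MSX1 at 1671.7 and 1586.2 against 3483.5 to 4796.4. MYCN went the other way, higher on the replicate 1 arrays, at 17261.6 and 16956.4 against 13622 to 15543. ZIC1 had a log2 difference of 0.15 for replicate 1 and 0.13 for treatment. CSRNP1 and LMO4 differed less by replicate 1, with log2 differences of -0.10 for both, against -0.61 and 0.26 for treatment. Of 33 neural crest genes above background, 22 were lower and 11 higher on the mean of the replicate 1 arrays, with a median log2 difference of -0.51. The central 95% of 10000 random lists matched on mean signal ran from -0.21 to 0.19. Their genes were drawn singly, while genes of a list can vary together, so this range may be too narrow. Surface ectoderm genes also varied from array to array: KRT7 was read at 590.5 on control 2 and 795.5 on homocysteine 2 and between 2548.4 and 3354.9 on the other 4. These genes were picked after their values were seen.

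The replicate 1 arrays stand apart in both groups. Loss of 5' signal in labelling would reach the spiked bacterial RNAs too, and their median change in log2 ratio of 5' to 3' signal was -0.199 (standard error 0.251 over 4 RNAs), against -2.50 for ACTB and -0.94 for GAPDH. The spiked RNAs ranged from 0.10 to -1.04, with lys falling more than GAPDH, and their 3' signal was lower by 1.23 in log2, so labelling stays open, though no spiked RNA fell as far as ACTB. Shorter RNA or cDNA in these samples may account for the split: both ratios were lower there than on every other array, by at least 0.494 in log2. Another mix of cells stays open as well, since 2 of 6 lists of other cell types, blood and endothelium and surface ectoderm, lay outside matched random lists. Of these only blood and endothelium moved together, with 10 of 12 genes higher; in surface ectoderm 9 of 14 were higher, and its medians per array (0.32, -0.70 and 0.67 in control, 0.045, -0.17 and 0.12 with homocysteine) were lowest on the replicate 2 arrays, so it does not mark replicate 1. The lower ribosomal and respiratory chain lists (medians of -0.19 and -0.36) lay outside too, as 12 of 32 lists did, so list shifts there do not separate cells from RNA quality.

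No probe set passed the threshold. The spread between arrays may account for missed changes of 2-fold. In simulated data the main fit called 0% of these, as did the fit restricted to probe sets above background. For 4-fold changes, simulated only in probe sets above background, the main fit called 0%. The restricted fit called 70.4% of simulated 4-fold changes and 0 real probe sets. The 0% of the main fit for 4-fold thus depended on the dim probe sets in the fit and its adjustment, and not on the spread between arrays alone. The share of 70.4% is for 200 changed probe sets at once, with moderated spreads and independent arrays. Fewer changed probe sets were not simulated, so this share does not carry over to a response of few genes. A response shared by the cultures but hidden by the split by replicate number would make the differences of the same-numbered pairs correlate. Across 9479 genes above background these differences correlated by 0.0476, 0.0367 and 0.019. This argues only against a shared response of many genes that is large against the spread of single arrays. A small response of many genes and a response of few genes stay open. The size of response that these correlations could detect was not tested. Of the 10 splits of the 6 arrays into 3 and 3, 10 gave as many probe sets past the threshold (0, highest other 0). As many lists came from 10 splits (0, highest other 3). With a real count of 0 every split gives as many, so both results were fixed in advance and decide nothing. At an unadjusted p under 0.05, 9 gave as many (1524, highest other 4395), and 10 splits are too few for a share under 0.05. The split with 4395 sets control 1, homocysteine 1 and homocysteine 3 against the rest, keeping the replicate 1 arrays together, which points to the structure of the samples.

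The ribosomal and respiratory chain lists leaned up and the adhesion and migration list down with homocysteine in the main fit. The ribosomal and respiratory chain medians were 0.0074 and 0.032 with quantile normalization and 0.025 and 0.0068 with centring, so their lean depends on the scaling. The adhesion and migration median was -0.0229 in the main fit, -0.0305 with quantile normalization and -0.0787 with centring, so it did not shrink. Across genes above background the treatment change hardly followed the difference of replicate 1 from the other arrays, with a correlation of 0.0455. This cannot decide whether RNA quality differed between the groups. Labelling or another mix of cells may lie behind the replicate 1 difference too. The GAPDH ratio of 5' to 3' signal was 0.663 on control 3 and 0.456 on homocysteine 3. In the other same-numbered pairs it was 0.318 and 0.324, and 0.685 and 0.694. A response to homocysteine shared by the cultures stays open: 0 of the 3 lists lay outside matched random lists, which does not exclude it. The pair medians of adhesion and migration genes were 0.013, -0.067 and -0.12. The ribosomal list, at 0.0049, 0.097 and 0.13, and the respiratory chain list, at 0.048, 0.12 and 0.016, leaned up in every pair. For ribosomal proteins the median was 0.0812 and the random lists gave 0.0362 to 0.0829, so other bright genes leaned up too.

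Over the treatment, 4 of 32 lists lay outside their matched random lists. Of these, extracellular matrix genes above background had a median of -0.11 and pair medians of -0.12, 0.015 and -0.067. Unfolded protein response genes above background had a median of -0.065 and pair medians of -0.024, -0.13 and 0.022, so in both the pairs did not agree in sign. All 26 measured unfolded protein response genes had pair medians of -0.053, -0.13 and -0.066, which agreed in sign. All 58 measured extracellular matrix genes had -0.11, 0.0079 and -0.094, which did not. Neuronal genes above background had a median of 0.25 and pair medians of 0.31, 0.05 and 0.34, and S phase genes a median of -0.07 and pair medians of -0.0055, -0.04 and -0.20, so in both the pairs agreed in sign. The S phase median ranged from -0.19 to 0.050 over leaving out each array. All 19 measured neuronal genes had pair medians of 0.21, -0.16 and 0 and a median of 0.16, or 0.0013 with the mean of all probe sets, so their pairs did not agree in sign. None of the 4 passed camera.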
